A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

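Each of the 8 arrays came as a scanner file with 10752 spots and as a column of a table of processed values. Per the file headers, the scanner files hold the mean intensity of each spot and the median intensity of its local background in Alexa 532 and Alexa 647, each scanned at a high and a low setting and not corrected for background. Per the file headers they also hold a spot confidence in percent. That confidence was 0 only at saturated spots, which are 1.61 to 2.30% of the spots in Alexa 532 and 3.68 to 7.56% in Alexa 647, and it was read as a measure of saturation. Spots not above background made up 1.83 to 24.9% in Alexa 532 and 13.3 to 21.5% in Alexa 647. The deposited table of processed values holds log10 ratios of Alexa 532 over Alexa 647 for every array, not turned for the dye exchange. This was found by setting its columns against the scanner files, where they correlated at 0.985 or more with the ratios of the uncorrected spot means, over unsaturated spots more than 100 above background in both dyes. Over all spots the correlation was 0.647 to 0.911. Its rows follow the position of the spots along the slide and not the numbering of the scanner files, in which order the correlation was 0.162 to 0.463. The column medians were 0.037 to 0.071 on the log10 scale, and 28.5 to 36.1% of the values of a column lay below 0. The columns are therefore not centred on 0, and how the authors normalised them is not given in the sources used here. The scanner software and the scan dates are not given in the sources used here either, so no batch could be tested. Per the labels' protocols, RNA was treated to remove DNA and its integrity was checked before labelling.

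Each probe was printed as 4 spots. A platform annotation paired 133 probes (532 spots) with 1 gene symbol each and 0 with several. The other 2555 probes are unnamed here. A gene table of the assembly ASM479960v1, of another strain, listed 133 of the 133 symbols and 0 of the annotation's gene identifiers. Its coordinates were not used, and no genome position is given.

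Spot means of the high-setting scan were corrected for background with limma's normexp method (offset 50) and normalised within each array by loess, with saturated spots kept. The 4 spots of a probe were averaged. Every log2 ratio was turned to sample over reference by the dyes in the labels. The 2 dye-exchanged arrays of an RNA sample were averaged, since they hold the same RNA, which left 4 values per probe. A limma model with oxygen and light as additive terms was fitted to these 4 values, with 1 residual degree of freedom and a prior of 2.44. Its residual is the interaction of oxygen and light together with noise. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the 2688 probes. Differences within a condition and the interaction have no degrees of freedom left and are given as values. Size counts took probes with a mean difference of at least 1 on the log2 scale and the same sign in both strata and both dye orientations. The interaction count took a difference of differences of at least 1 with the same sign in both orientations. With 1 culture per condition, p-values measure the spread between these 4 samples only.

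Of 23 gene lists fixed by gene symbol, 15 had a measured member and 9 had at least 3 and were tested with camera (preset correlation 0.01), adjusted over the 9 lists and both contrasts. The lists of gas vesicles, DMSO reductase, terminal oxidases, ATP synthase, archaellum, RNA polymerase, general transcription factors and transposases had no member with a symbol. The rpmC gene falls outside the symbol pattern of the ribosomal list. The rule for named genes took the 12 highest and 12 lowest probes per contrast with the same sign in both strata and both orientations, filled with values where fewer were called, together with htr8, pyrF, bop, bat, gvpA, arcA, arcB, dmsA and up to 4 members of each list with the largest differences. For the interaction it took 6 in each direction. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

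The comparison with the reference was added after the data were examined. It fitted an intercept to the 4 sample values in limma (3 residual degrees of freedom, prior 1.89) and tested it against 0, with its lists adjusted as a separate family of 9. The genes infB, hutI and rpmC fall outside the lists, and rpmC is among the 24 probes the same rule selects for this comparison, as is htr8. The other 2 were chosen after their values were seen.

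The fits were tested on simulated arrays with 200 probes changed. These used the real dye effects and the variances of the oxygen and light fit after limma's prior was applied. The real means were used for oxygen and light but not for the reference. For oxygen, 84 of 100 probes changed by 0.5 on the log2 scale and 100 of 100 changed by 1 were called, and 11.1% of the calls were false. For light, 69 of 100 and 99 of 100 were called, with 9.19% false. For the reference, 98 of 100 and 100 of 100 were called, with 5.26% false. A shift of 0.5 in the 6 transducers for oxygen was called by camera, as was the rhodopsin list, which shares 2 of them. The simulation starts after normalisation and does not include its errors. The 2 arrays of a simulated pair differed only by a dye effect that all pairs shared, without error of their own.

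The alternatives tried were other background corrections, other normalisations, a filter on dim probes, medians of spots, the authors' values, other models of the dye exchange, each dye orientation alone, arrays and RNA samples left out in turn, other variance priors, other list tests and a lower size threshold. Print-tip loess, the low-setting scans, 2 treatments of saturated spots and single arrays left out without background correction were added after the data were examined. R 4.3.3 and limma 3.58.1 were used.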

Results

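Transcript levels of the halophilic archaeon Halobacterium salinarum NRC-1 were measured on 8 two-colour arrays, with a strain deleted for htr8 and ura3. The gene htr8 encodes a membrane transducer of the Htr family, which relays sensory stimuli to the chemotaxis proteins, and ura3 (listed as pyrF) encodes orotidine phosphate decarboxylase of uracil synthesis. Cultures of 50 mL in 125 mL flasks were grown in rich medium to mid-log phase under high oxygen (shaking at 210 rpm) or low oxygen (100 rpm), each in light and in the dark. This gave 4 RNA samples, 1 per condition. Each was hybridised on 2 arrays with the dyes exchanged, against a common reference of mid-log NRC-1 RNA. The exchanged arrays hold the same RNA and count as 1 replicate, so no condition had a replicate culture. The number of arrays limits the precision. The median spot was 1.33 to 2.09 times its local background in Alexa 532 and 1.53 to 2.04 times in Alexa 647.

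Each array held 2688 probes, of which 133 carried a gene symbol here. The other 2555 are unnamed and are given by probe number. No probe with a symbol stood for bop, gvpA, arcB or dmsA. All values below are log2 ratios of sample over reference, or differences between them, ± the limma standard error (SE).

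The deleted genes were read first, as a check of the labels. The htr8 probe lay below the reference by 0.93 on the log2 scale (−0.93 ± 0.058), a ratio of 0.526, and it was below the reference on 8 of 8 arrays. The adjusted p of limma was 0.0047. The values of the 8 arrays ran from −1.36 to −0.61. The probe of pyrF read −0.33 ± 0.145 with an adjusted p of 0.178 in limma, which did not pass. It was below the reference on 7 of 8 arrays and 1.04 above it on the array of the high-oxygen light sample that carried the sample in Alexa 532. Whether the probes lie inside the deleted stretches is not known here, and a deleted gene did not read as absent on these arrays.

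The comparison of low with high oxygen asked which transcripts differ with the oxygen supply of the culture, over the light and dark samples together. No gene passed. Among the genes with a symbol, hutI (imidazolonepropionase of histidine breakdown) had the largest difference, −0.51 ± 0.15, and it was chosen for mention after its value was seen. The gene bat, a regulator of the bacteriorhodopsin gene, read −0.28 ± 0.093 overall but −0.69 on the arrays with the sample in Alexa 532 and 0.13 on those with it in Alexa 647. The mismatch repair gene mutL read −0.29 ± 0.085, with −0.30 in light and −0.28 in the dark. The unadjusted p was 0.037, 0.048 and 0.034 for these 3 genes in limma, and the adjusted p was 0.945 for each.

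The gene lists fixed beforehand showed small oxygen differences. All 4 measured chemotaxis genes lay below 0, with cheA, the histidine kinase, and cheY, its response regulator, at −0.11 ± 0.097 each, cheR at −0.05 and cheB at −0.03. Their median of −0.08 did not pass (camera adjusted p = 0.973). Of the 6 Htr transducers other than htr8, 4 lay above 0 and 2 below, from htr4 at 0.17 ± 0.093 to htr18 at −0.20 ± 0.11. The light receptor and pump genes read 0.06 for sop1, which encodes sensory rhodopsin I, −0.03 for sop2 (sensory rhodopsin II) and −0.02 for hop (halorhodopsin). In the TCA cycle, mdh (malate dehydrogenase) read 0.05 ± 0.091, citZ (citrate synthase) 0.02 ± 0.088, and sucC, a subunit of succinyl-CoA synthetase, −0.04 ± 0.085. The arginine deiminase pathway, which ferments arginine, was represented by arcA at 0.06 ± 0.084 and arcC at −0.04 ± 0.14. Respiratory chain members nuoL and sdhC read −0.06 each. In cobalamin and haem synthesis, cobN read 0.13 and hemA −0.09. For nucleotide synthesis 4 members lay above 0 and 7 below, among them purB at −0.16 ± 0.37 and purM at 0.13 ± 0.085. The glycolytic gene eno read −0.08, the ribosomal protein gene rpl12p −0.06, the methionine sulfoxide reductase gene msrA 0.07 and the phosphate regulator gene phoU −0.02. The chaperone and proteasome list had psmA at −0.08 and pan1 at 0.07, and its symbol rule also took in panB, a gene of pantothenate synthesis, at 0.16.

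The limma fit called 0 of 2688 probes for oxygen, with 110 at an unadjusted p under 0.05 where chance gives 134, and the smallest adjusted p was 0.945. The count of 110 became 30 to 344 when 1 array was left out in turn. None of the 9 tested lists was called, with an adjusted p of 0.973 for each by camera, although the TCA and chemotaxis lists were called on the low-setting scans. In the lists too small to test, no gene other than bat passed adjusted over its list alone. The gene bat is the only measured member of its list, so its unadjusted p stands there without any adjustment. The median and the direction of camera had different signs for the transducers, DNA repair, nucleotide synthesis and the chaperone list. By size, 1 probe differed at least 2-fold with the same sign in both light states and both dye orientations. That probe, 2075, read −1.27, is unnamed and lies at percentile 4.69 of intensity. The 24 probes that the naming rule selected hold 0 with a symbol and 23 below the median intensity. On simulated arrays with 200 changed probes, 84 of 100 changed by 0.5 on the log2 scale and 100 of 100 changed by 1 were called. Their noise used variances after limma's prior was applied, and many changed probes together make the adjusted threshold easier to pass. The simulation therefore cannot tell whether a few changes of this size would be called here. In the real fit, probe 1617 at −0.86 ± 0.0997 had an adjusted p of 0.945 in limma.

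The comparison of light with dark asked which transcripts differ with illumination, over both oxygen states. No gene passed here either. The purine synthesis gene purB had the largest difference of the genes with a symbol, 0.86 ± 0.37, with 1.53 at high oxygen and 0.19 at low oxygen, and it read 1.87 on the arrays with the sample in Alexa 532 against −0.14 on the others. The DNA repair genes went in opposite directions, with uvrA, of nucleotide excision repair, at −0.32 ± 0.088 and mutL at 0.31 ± 0.085. The deleted gene pyrF read 0.54 ± 0.17, with 0.97 on the arrays with the sample in Alexa 532 and 0.11 on the others.

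The genes tied to light sensing differed little. The 5 members of the sensory rhodopsin and halorhodopsin list all lay below 0, with htr2 at −0.07 ± 0.087, htr1 at −0.04, hop at −0.03 and sop1 at −0.02, where htr1 and htr2 encode the transducers of the sensory rhodopsins. The regulator bat read 0.14 ± 0.093. The 4 chemotaxis genes lay above 0, from cheB at 0.0063 to cheY at 0.09 ± 0.097. Of the transducers, htr4 read 0.17, htr18 −0.10 and htr7 −0.07. The 5 TCA cycle genes lay below 0, with citZ at −0.13 ± 0.088 and mdh at −0.10. In nucleotide synthesis, purL read 0.17 and purF 0.13. The proteasome ATPase gene pan1 read −0.24 ± 0.086, the chaperone genes dnaJ and dnaK −0.08 and 0.08, and the pantothenate gene panB 0.22. The values of cbiT (−0.11), arcC (0.10), arcA (−0.06), nuoL (−0.12), sdhC (0.12), rpl12p (0.14), phoU (0.18), msrA (−0.07) and ppsA (0.06) were of similar or smaller size.

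For light, limma called 0 of 2688 probes, with 313 at an unadjusted p under 0.05 and a smallest adjusted p of 0.394. No list was called by camera (adjusted p = 0.973 for each). By size, 2 unnamed probes differed at least 2-fold, 5121 at 1.13 and 1983 at 1.11, at percentiles 7.11 and 16.8 of intensity. Their sizes differed between the dye orientations. Probe 5121 read 1.71 on the arrays with the sample in Alexa 532 and 0.54 on the others, and probe 1983 read 2.17 and 0.052. Of the 24 probes under the naming rule, 0 had a symbol and 22 lay in the lowest 25% of intensity. The count without background correction was 185, and with 1 array also left out in turn it was 0 for 6 of the 8 arrays, 316 without the low-oxygen light array with the sample in Alexa 532 and 413 without the low-oxygen dark array with it in Alexa 647. The log2 ratios of the high-oxygen light array with the sample in Alexa 532 had an SD of 0.652, against 0.295 to 0.365 on the others.

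**Figure D1:**
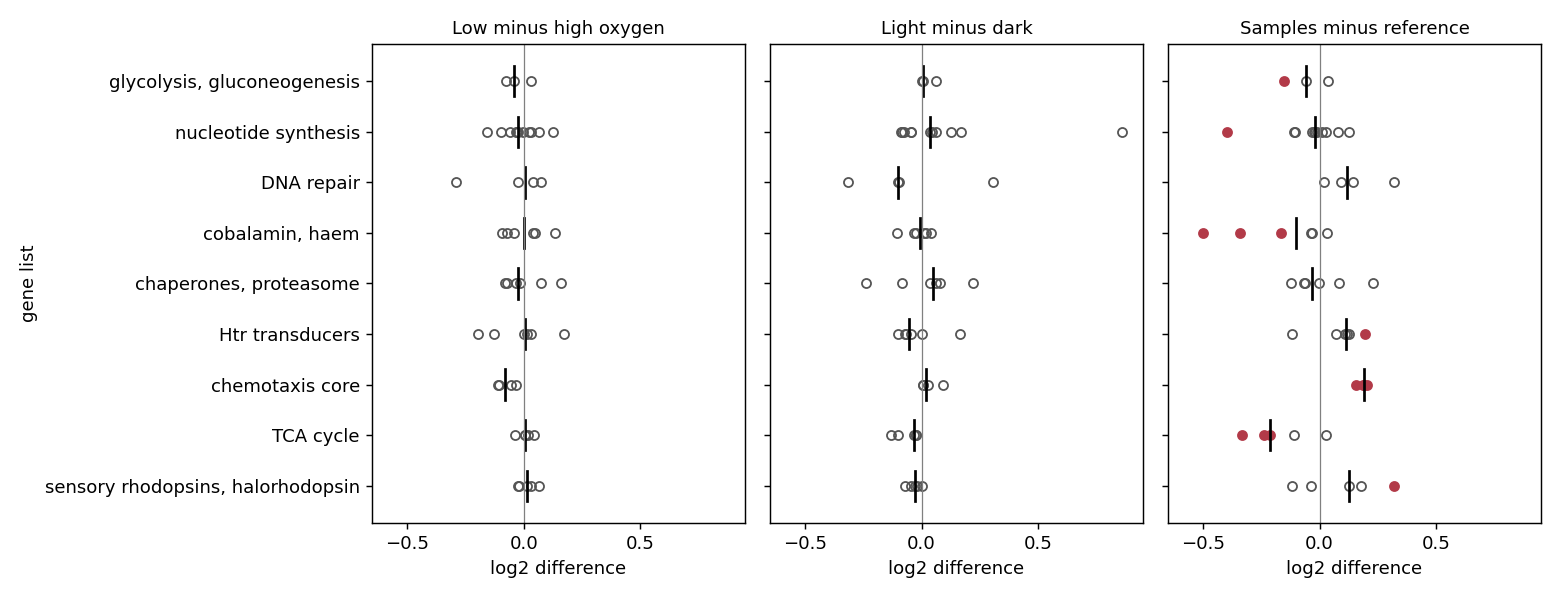
Log2 differences of the genes in the 9 tested lists for low minus high oxygen, light minus dark, and samples minus reference. Each circle is a gene, filled red where limma called it at an adjusted p under 0.05, and the black line is the median of the list. No gene is filled in the oxygen and light panels, while the 4 chemotaxis genes are filled above 0 in the reference panel.

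Within the separate conditions only values can be given, since each difference rests on 1 RNA sample against 1. The largest oxygen differences of list genes within light were −0.83 for purB and −0.35 for bat, while purB read 0.52 and bat −0.21 in the dark. Of the transducers, htr18 read −0.34 in light and −0.06 in the dark, and htr4 0.10 and 0.25. The light difference of arcC was 0.30 at high and −0.11 at low oxygen. For 61 probes the oxygen difference changed by at least 2-fold between light and dark with both dye orientations of the same sign, 7 with a higher value in light and 54 with a lower one. The largest were probe 4335 at −2.50 and probe 3261 at 1.31. The 12 probes named by the rule hold 0 with a symbol and 12 below the median intensity, and the count was 1 when the dimmest 25% of the probes were left out.

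The dye-exchanged arrays of an RNA sample did not follow each other over the probes. The correlation of their log ratios, both turned to sample over reference, was 0.036 for high oxygen in light, −0.064 for high oxygen in the dark, −0.142 for low oxygen in light and −0.191 for low oxygen in the dark. Over the brighter 1344 probes it was 0.126, 0.247, −0.0021 and 0.103. The oxygen difference from the arrays with the sample in Alexa 532 correlated at −0.218 with that from the other orientation, and the light difference at 0.141. These correlations are across probes, which are not independent replicates.

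**Figure D2:**
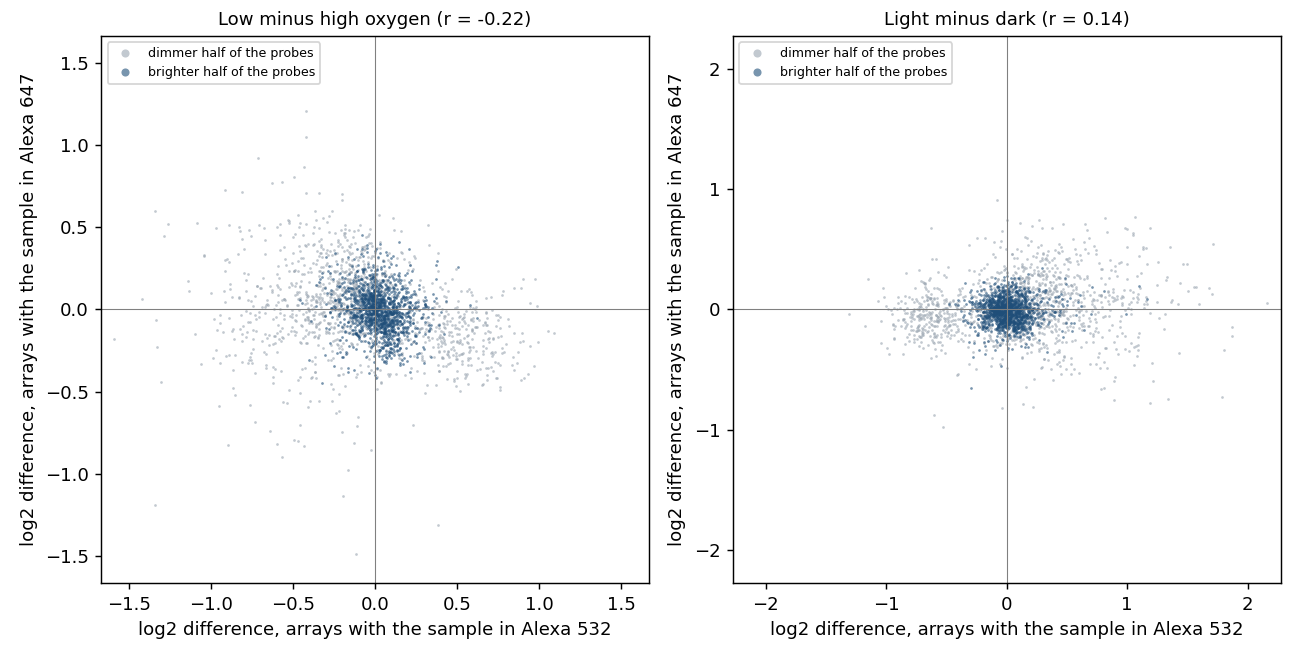
Each point is a probe, with the log2 difference from the 4 arrays that carried the sample in Alexa 532 on the x axis and from the 4 arrays that carried it in Alexa 647 on the y axis. Points of the brighter 1344 probes (blue) gather around 0, and the correlation over all probes is −0.22 for oxygen and 0.14 for light.

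The 4 samples of the deletion strain were also compared with the NRC-1 reference, a comparison added after the data were examined. It asks which transcripts stood apart from the reference in the mean of the 4 conditions. The strain differs from the reference together with whatever else differed between the cultures, all of which are labelled mid-log. The ribosomal protein genes rpmC (−0.63 ± 0.031) and rpl12p (−0.56 ± 0.051) and the initiation factor gene infB (−0.38 ± 0.044) were lower, and no list of such genes was tested. Of arginine fermentation only arcC and arcA were measured, too few for a list test, and they were higher by 0.45 ± 0.060 and 0.29 ± 0.036. Higher also were hop at 0.32 ± 0.031 and htr6 at 0.20 ± 0.030. The adjusted p of limma ran from 0.0030 for rpmC to 0.017 for htr6, and arcA, hop, htr6 and arcC lay above the reference on 8 of 8 arrays.

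All 4 measured chemotaxis genes were higher than the reference, cheY at 0.20 ± 0.048, cheB, the methylesterase, at 0.19 ± 0.032, cheA at 0.19 ± 0.044 and cheR, the methyltransferase, at 0.16 ± 0.035. Each passed over all probes and adjusted over the list alone, and the list was called by camera (adjusted p = 0.034, and adjusted p = 0.462 with an estimated correlation). Of the 5 TCA cycle genes, 3 were lower, sucC at −0.33 ± 0.032, mdh at −0.24 ± 0.042 and citZ at −0.21 ± 0.044. The value of sucD was −0.11 and that of icd 0.03, neither of which passed, and 4 genes passed adjusted over the list alone. The TCA list was called as lower (camera adjusted p = 0.034, and adjusted p = 0.462 with an estimated correlation). In cobalamin and haem synthesis 3 of 6 genes were lower, hemA, for glutamyl-tRNA reductase, at −0.50 ± 0.040, cbiT at −0.34 ± 0.049 and cbiG at −0.17 ± 0.036, and the list was called as lower (camera adjusted p = 0.045, and adjusted p = 0.462 with an estimated correlation). The genes hemL, cbiQ and cobN read −0.03, −0.04 and 0.03 without passing. The value of cbiG turned to 0.15 when only the arrays with the sample in Alexa 647 were used.

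None of these 3 lists was called without the dimmest 25% of the probes, on either dye orientation alone or on the low-setting scans, nor without the first (Alexa 532) array of the low-oxygen light or low-oxygen dark sample, nor without the high-oxygen light or the high-oxygen dark sample. The cobalamin and haem list was also not called with plain background subtraction, median centring, medians of spots, print-tip loess or either treatment of saturated spots, nor without any of 4 further single arrays or the low-oxygen light sample. Among random lists matched in intensity, the median of this list lay at percentile 7.57, that of the TCA list at 1.5 and that of the chemotaxis list at 98.07. The chemotaxis list was also not called with the authors' values or print-tip loess.

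The other lists were not called by camera, although that of glycolysis and gluconeogenesis was with the authors' values. The fry test called 7 of the 9 tested lists. Camera sets a list against the other probes, while fry asks only whether its genes differ from 0, so the counts are not alike. Of the 6 transducers, htr6 alone passed over all probes and 3 passed adjusted over the list alone, with htr1 at 0.13 ± 0.032 and htr2 at −0.12 ± 0.036 on opposite sides of the reference. In the rhodopsin list hop passed over all probes and 4 of 5 genes adjusted over the list alone, and sop1 read 0.18 ± 0.053 and sop2 −0.04. Of 11 nucleotide synthesis genes carB, the large subunit of carbamoyl phosphate synthetase, was lower at −0.40 ± 0.035, while purE read 0.13 ± 0.034. In glycolysis tpiA was lower at −0.15 ± 0.031, although it read 0.0093 on the arrays with the sample in Alexa 532 alone. The DNA repair genes all lay above 0, with mutL at 0.32 ± 0.10 and uvrB at 0.14 ± 0.040, and none passed over all probes but 2 of 4 adjusted over the list alone. The chaperone and proteasome genes pan1 (0.23 ± 0.064) and dnaK (−0.12 ± 0.036) did not pass, nor did bat at 0.13 ± 0.079, phoU at −0.14 ± 0.053, sdhC at −0.10 or msrA at 0.07.

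**Figure D3:**
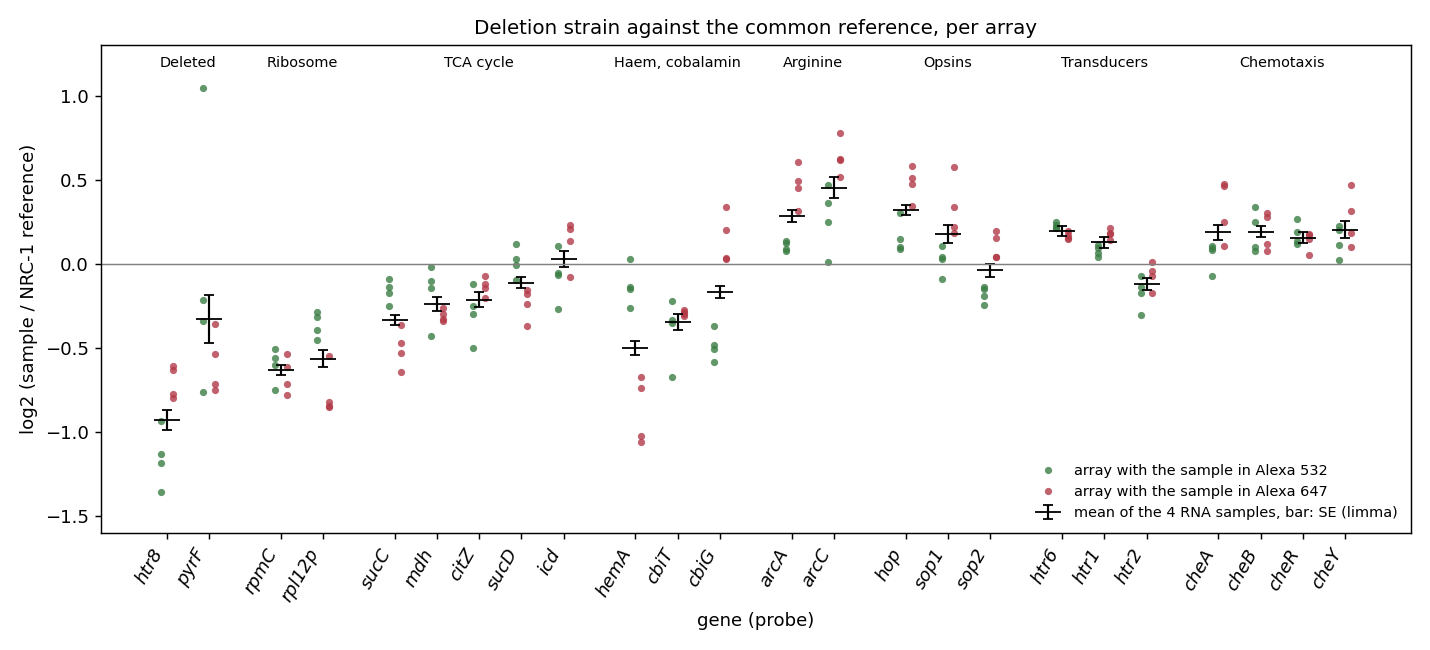
Log2 ratio of sample over the NRC-1 reference for named genes, with 1 point per array, coloured by the dye that carried the sample (4 green and 4 red points per gene). The black line is the mean of the 4 RNA samples with the SE of limma. The 8 points of rpmC lie below 0 and those of cheB above 0, while hemA and cbiG differ between the dyes by more than the SE.

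In all, limma called 577 of 2688 probes against the reference, 309 higher and 268 lower, and 36 of the 133 genes with a symbol, 13 higher and 23 lower. The unnamed probes farthest from the reference were 4433 at −1.80 and 5161 at −1.19 on the lower side and 1017 at 0.94 and 553 at 0.79 on the higher side. The test is of the ratio against 0 and leaves out the spread of the reference itself. The count fell to 17, 12 and 19 without the high-oxygen dark, the low-oxygen light or the low-oxygen dark sample, while it was 460 without the high-oxygen light sample and 38 on the low-setting scans. Without 1 array it was 195 and 257 for the Alexa 647 arrays of the high-oxygen light and the high-oxygen dark sample, and 351 for the Alexa 532 array of the low-oxygen light sample.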

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

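The tests of the light pattern that rest on a left-out array and on the brighter probes were set before their results were seen, as was the test of swapped dye labels, and the others in this part, with the intensity trend among them, were chosen after.

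Among the 58 genes of the fixed lists with htr8 and pyrF, the oxygen difference had opposite signs in light and in the dark on both dye orientations for 8 genes. The light difference had opposite signs at high and low oxygen for 10 genes. Independent signs would give 7.25 each, and none of these differences was tested, since each rests on 1 RNA sample per condition. The differences of differences for oxygen were −1.34 for purB, −0.18 for rpl12p, 0.41 for htr8, 0.28 for pyrI, −0.18 for purL, −0.36 for sop1, −0.21 for sop2 and 0.20 for radB. For light they were 0.41 for htr8, 0.25 for cbiT, 0.32 for icd, −0.30 for dnaJ, 0.28 for pyrI, −0.41 for arcC, −0.36 for sop1, −0.21 for sop2, −0.17 for cheA and −0.28 for cobN.

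The first pattern is the lack of correlation between dye-exchanged arrays. Swapped dye labels are argued against, because every array, with the dye bias of the other pairs removed, correlated above 0 with the mean of the other 3 RNA samples (lowest 0.16). Dim spots alone are argued against by a pair with a correlation of −0.0021 over the brighter 1344 probes. A dye bias of each probe alone stays open, with a median correlation of 0.095 after its removal over all probes and pairs on both sides of 0.1. With the bias removed and over the brighter probes, the lowest pair reached 0.533, so a shared dye bias together with spots close to background may account for the pattern. No biological explanation was tested, since both arrays hold the same RNA.

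The second pattern is that 313 probes had an unadjusted p under 0.05 for light and 110 for oxygen, where chance gives 134. Without the high-oxygen light array that carried the sample in Alexa 532, the light count was 128. It was also 93 without the other array of that sample, 112 and 142 without the low-oxygen light array in Alexa 647 and the low-oxygen dark array in Alexa 532, and 243 to 603 without 1 of the others. These counts do not single out an array, so the part of that array cannot be told. With 1 array left out in turn, the oxygen count ran from 30 to 344. It exceeded the light count without the Alexa 532 array of the high-oxygen light sample (153 against 128) or of the high-oxygen dark sample (327 against 254). Without any other array it stayed below the light count. In the brighter 1344 probes 0.967% were at an unadjusted p under 0.05 for light. The variance pooled over all probes lowers that share, and with an intensity trend in the prior it was 9.08% (7.59% for oxygen). In the dimmer probes the light share was 22.3% (7.89% for oxygen), and 17.0% with the trend (3.87% for oxygen). With either prior, the excess of light over oxygen therefore lay mostly in the dimmer probes. These shares do not tell noise from an effect at dim probes, so noise at spots close to background stays open. An effect of light on transcripts stays open as well, since each condition has 1 sample. Each dye orientation alone gave 108 probes for light, against 63 for oxygen with the sample in Alexa 532 and 164 with it in Alexa 647. The 8 arrays with dye orientation as a block gave 105 for light and 61 for oxygen, in a fit that counts arrays of the same RNA as replicates.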

How the results depend on the processing

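No gene was called for oxygen under any of the alternatives run except without background correction, where 3 probes were, and 66 when the low-oxygen dark array with the sample in Alexa 647 was also left out. For light the count was 185 without background correction (with 1 array also left out in turn, 0 for 6 of the 8 arrays and 316 and 413 for the others), 14 with an intensity trend in the prior and 1 on the low-setting scans, and 0 otherwise. With the background corrected, leaving out each array or RNA sample in turn gave 0 to 0 calls for oxygen and 0 to 0 for light, and 0 to 0 lists for both. The count against the reference was 1050 with all 8 arrays and the RNA sample as a random block. The consensus correlation within a block was −0.444 there, and a negative value lowers the SE of the block mean. The count was 375 and 1068 with only the arrays with the sample in Alexa 532 and in Alexa 647. On the low-setting scans it was 38, where 23.7% of the calls were higher against 53.6% in the main setting. With an array or a sample left out it was 12 to 514, and 369 to 710 with an array left out and no background correction. A fit of the array-level ratios with dye orientation as a block counts the 2 arrays of an RNA sample as separate replicates. It gave a count against the reference of 564, and 0 for oxygen and light. For at least 2-fold differences in oxygen, light and the interaction they were 0, 0 and 0 without background correction, 53, 91 and 194 with plain subtraction, 0, 0 and 1 without the dimmest 25% of the probes and 0, 0 and 0 with the authors' values. The light count was 6 with an offset of 10, 0 with median centring, 1 with scaling between arrays, 4 with medians of spots and 1 with print-tip loess, and the interaction count was 36 with median centring and 28 on the low-setting scans. A threshold of 1.5-fold gave 26 for oxygen and 71 for light.

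For the lists, 2 (TCA cycle and chemotaxis, both for oxygen) were called on the low-setting scans and 0 in the other settings for oxygen and light. Against the reference 0 were called with the estimated correlation, without the dimmest 25% of the probes, with each dye orientation alone and on the low-setting scans, 1 with print-tip loess, 7 by fry, and 0 to 3 with an array or sample left out. The median correlation of the dye-exchanged pairs was −0.103 in the main setting, −0.290 with median centring, 0.033 without the dimmest 25%, −0.406 with the authors' values and 0.052 on the low-setting scans. With the background corrected, the value of htr8 was −0.97 to −0.88 with an array or sample left out and that of pyrF −0.53 to −0.12. The value of pyrF passed at −0.59 on the Alexa 647 arrays alone, at −0.53 without the high-oxygen light array with the sample in Alexa 532, at −0.49 without both arrays of that sample, and at −0.35 without that array and without background correction. Of the genes compared with the reference, cbiG read 0.15 and thiC −0.010 on the Alexa 647 arrays alone, tpiA 0.0093 and argH −0.018 on the Alexa 532 arrays alone, and icd −0.16 with the authors' values. The counts of gene values that follow are not counts of genes. Each value is 1 tracked gene in 1 alternative setting, so a gene is counted once per setting. Of the other values tracked against the reference, 1113 stayed on their side of the threshold (10 of them uncalled and with a changed sign). A further 286 no longer passed and 34 newly passed. Of the values of 1 tracked gene in 1 setting for oxygen and for light, 2401 and 2394 stayed uncalled. Of these, 395 and 318 changed sign, and 7 further values for light newly passed. Leaving out an RNA sample lowers the degrees of freedom equally for each sample. The count against the reference was still 460 without the high-oxygen light sample and 12 to 19 without each of the others. The cause of the shifts was not tested. The alternative of ignoring flags could not be run, since the files mark only saturation, and leaving out saturated spots was run in its place. Signal close to background limits the dim probes.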

Other observations

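The groups in this part were picked from the gene symbols after the data were examined, and so were the genes named in it. The test of the aminoacyl-tRNA synthetases and that of strain and culture were chosen after the values were seen, and those of saturation and of the single-array signs before.

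Genes outside the fixed lists also differed from the reference. The urocanase gene hutU of histidine breakdown was higher (0.45 ± 0.092), and so was argH, argininosuccinate lyase (0.33 ± 0.033), although argH read −0.018 on the arrays with the sample in Alexa 532. Lower were thiL (−0.37 ± 0.048), gyrA, a DNA gyrase subunit (−0.34 ± 0.050), cmk (−0.33 ± 0.037), speB (−0.33 ± 0.058), folP (−0.32 ± 0.050) and gdhA1, a glutamate dehydrogenase (−0.29 ± 0.042). Of the 6 histidine synthesis genes hisI (−0.25 ± 0.040) and hisF (−0.18 ± 0.039) were lower and hisG (0.14 ± 0.033) was higher. Of the 12 aminoacyl-tRNA synthetase genes 10 lay below the reference, and lysS passed (−0.23 ± 0.036). For oxygen, nadC, of NAD synthesis, read −0.37 ± 0.084, with −0.37 in light and −0.37 in the dark, but its adjusted p in limma was 0.945. The origin recognition genes orc7 and orc8 read 0.17 ± 0.085 and 0.18 ± 0.092, and gyrA 0.17 ± 0.086, and none was called. Each had the same sign in both light states and both orientations, as had 35 of the 133 genes with a symbol.

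One hypothesis was that the aminoacyl-tRNA synthetase genes are higher as a group at low oxygen. Of the 12, 10 lay above 0, with a median of 0.064. The group was not called by camera (p = 0.0528, and p = 0.290 with an estimated correlation), so the hypothesis was not borne out, which does not show that the levels were equal. Of the other groups picked for oxygen, the 3 histidine utilisation genes hutG, hutI and hutU had a median of −0.309 (camera p = 0.0337, and p = 0.432 with an estimated correlation) and the 6 histidine synthesis genes a median of 0.0020 (camera p = 0.968). These p values were not adjusted over the groups.

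The pattern a reader may want to follow up is the set of 36 genes with a symbol called against the reference. On the low-setting scans 97.2% of them (35 genes) kept their sign, so for these no turn of sign between the scans was seen. That share counts genes with and without saturated spots together, so it cannot decide what saturation did to the saturated ones. The sign does not test the size or the call. The median size of change of the 36 genes on the low-setting scans was 0.69 of that in the main setting. Over all probes 38 were called there, against 577. With saturated spots left out 474 were called, 472 of them also called in the main setting with the same sign. A dye bias shared by all arrays cancels by design in the mean of each dye-exchanged pair. Whether another dye bias is left in that mean cannot be told. After removal of the bias of the other pairs 83.3% (30 genes) had the same sign in all 8 single-array readings, which does not test the mean. The deletion of htr8 cannot be told apart from that of ura3 or from another difference in strain or in culture from the reference. Every sample carried both deletions, and 0 RNA samples of an undeleted strain were among the samples.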
